A study of Mus musculus with 21 samples.

How the data were processed

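Total RNA came from the snap-frozen whole left lung of female BALB/c mice, isolated with a column kit, and biotin-labelled cRNA was hybridised, per the labels' protocols. The labels call each array a biological replicate. Each array gave 1 column of values for 22690 probe sets with Affymetrix-type names. The deposited values are intensities on a linear scale, with 9.38% to 11.2% of the values of an array below 0, so a background or mismatch signal had been subtracted. The scanner software, the summary method and any scaling are not given in the sources used here. The median intensity of the arrays differed by up to 3.08 times, so the deposited intensities had not been brought to one level. For arrays, the number of arrays limits the precision. No 2 arrays held identical values (0 pairs), and the highest correlation within a group was 0.992.

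The design fixed beforehand took linear values as log2(value + 16) with no scaling. Because the arrays proved unscaled, the intensities were quantile normalized between arrays after 64 control probe sets were left out, values below 0 were set to 0, and log2(value + 16) was taken. The unscaled values are an alternative chosen after seeing the data. Folds are on the log2(value + 16) scale, which understates the change of dim genes. The noise level was the 95th percentile of the size of the values below 0 (intensity 40.9, log2 5.83). A gene under that level on every array of 1 group was given as at least N-fold, the other group's mean against the higher of the noise level and the dim group's own values, and no fold was given where both groups were under it. Where a group's mean but not every array lay under it, the fitted fold rests in part on noise.

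Of 22626 probe sets, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Symbols were updated by gene number through the reference gene table of assembly GRCm38.p6, which held 20364 of these probe sets, and 29 kept an older symbol. For each of 12393 genes the brightest probe set over all arrays was used, and 4958 genes had more than 1. Other probe sets of a named gene passed the threshold in the opposite direction for 1 gene, Per3, for MACA against HBSS at 12 h.

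limma (3.58.1, with R 4.3.3) fitted 6 group means to the 21 arrays, with 15 residual degrees of freedom. The 10 comparisons were MACA against HBSS, BSA against HBSS and MACA against BSA at each time, 12 h against 3 h for each treatment, and the change of the MACA to HBSS difference between times. Benjamini-Hochberg adjusted p under 0.05 within a comparison was the threshold. Figures used python 3.11.15 and matplotlib 3.10.9. The groups, comparisons, tests, gene lists, naming rule and most other settings were fixed before the data were examined. The rule for named genes took, for MACA against HBSS and against BSA at each time, the 12 highest and 8 lowest log2 folds past the threshold whose groups did not overlap, and for the other comparisons the 5 highest and 5 lowest. For each list it took up to 4 members with the largest change past the threshold in MACA against HBSS at each time and up to 2 that did not pass. Genes outside the rule are said to be chosen after their values were seen.

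The 33 gene lists held 634 genes, 551 of them measured, and some genes stand in more than 1 list. They were CXC chemokines, CC chemokines, proinflammatory cytokines, NF-kB feedback genes, pattern recognition receptors, acute phase and antimicrobial genes, STAT and SOCS feedback genes, interferon-stimulated genes, type 2 and alternative activation genes, oxidative stress and metallothionein genes, immediate early genes, glucocorticoid-responsive genes, circadian clock genes, cell cycle genes, MHC class II genes, complement genes, coagulation and fibrinolysis genes, endothelial adhesion and activation genes, prostaglandin and leukotriene genes, matrix and remodelling genes, neutrophil markers, macrophage and monocyte markers, eosinophil, basophil and mast cell markers, T cell and NK cell markers, B cell and plasma cell markers, dendritic cell markers, alveolar epithelial markers, airway epithelial markers, endothelial cell markers, fibroblast and smooth muscle markers, erythroid and platelet markers, cardiac muscle, skeletal muscle, fat and cartilage markers and thymus and lymph node markers. Camera (limma, preset correlation 0.01) tested each list against all other genes, 2-sided, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives.

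A technical set was found in the values: the ratio of 2 probe sets of 1 spiked hybridization control was 1.62 to 1.91 in 13 arrays (high set) and 0.939 to 1.22 in 8 arrays (low set). The low set held MACA 3 h replicates 3 and 4, BSA 12 h replicates 3 and 4 and all 4 HBSS 12 h arrays. A fit with the set as a term and fits within each set were added after seeing the data. Genes given as shared passed both that fit and the fit of the 6 group means, with the same direction.

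Replicate numbers in the labels were checked for pairing through the correlation of same-numbered arrays' deviations from their group means. For BSA against HBSS at 12 h all 4 pairs correlated at 0.14 to 0.34, so these numbers were taken to pair the arrays, from the values and not from the labels. The 4 other pairs within replicates 1 and 2 or 3 and 4 correlated at 0.09 to 0.24, the 8 across these at -0.30 to -0.05, and 2 of the 4 numbered pairs best with their own number, so the values part replicates 1 and 2 from 3 and 4. Each of the other comparisons had a pair under 0.1.

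The other settings tried were quantile normalization of log2 values, median centring, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, all probe sets singly, only the groups compared, a variance trend with robust estimation, array weights, the replicate block, log2(value + 1) and log2(value + 64), and leaving out each array. Comparisons that shared arrays were set beside 10 simulations of unchanged groups. The steps were tested on simulated data with 200 of 12393 genes changed. For MACA against HBSS at 3 h the test recovered 32% of genes changed by log2 0.5, 80% by log2 1 and 100% by log2 2, with 8.47% of calls false. At 12 h it recovered 28%, 80% and 98%, with 5.17% false, and for BSA against HBSS at 3 h 34%, 84% and 98%, with 7.22% false.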

Results

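Gene expression was measured in the whole left lung of female BALB/c mice after 1 aspiration into the trachea. The mice, 8 weeks old, received MACA, a crude antigen extract of the fungus Metarhizium anisopliae (20 µg in 50 µl), bovine serum albumin (BSA) at the same dose, or the vehicle, Hank's balanced salt solution (HBSS), alone, and lungs were taken 3 h or 12 h later. The 21 arrays fell into 6 groups: MACA 3 h (n = 4), BSA 3 h (n = 3), HBSS 3 h (n = 3), MACA 12 h (n = 3), BSA 12 h (n = 4) and HBSS 12 h (n = 4). The median deposited intensity of an array ranged from 93.0 to 287, and the number of arrays limits the precision of every comparison. The labels speak of agents of high or low allergenicity. The comparisons ask which lung transcripts differ after the fungal extract, after a foreign protein and after vehicle at each time.

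Arrays of one group correlated at a median of 0.988, and arrays of different groups at a median of 0.978. The first principal component took 23.6% of the variance and the second 15.1%. The 7 MACA arrays scored 18.8 to 28.7 on the first component, and on the second all 3 h arrays were positive and all 12 h arrays negative. BSA 12 h replicate 1 lay at 8.47 on the first component, and the other 3 BSA 12 h arrays between -16.2 and -11.2.

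**Figure D1:**
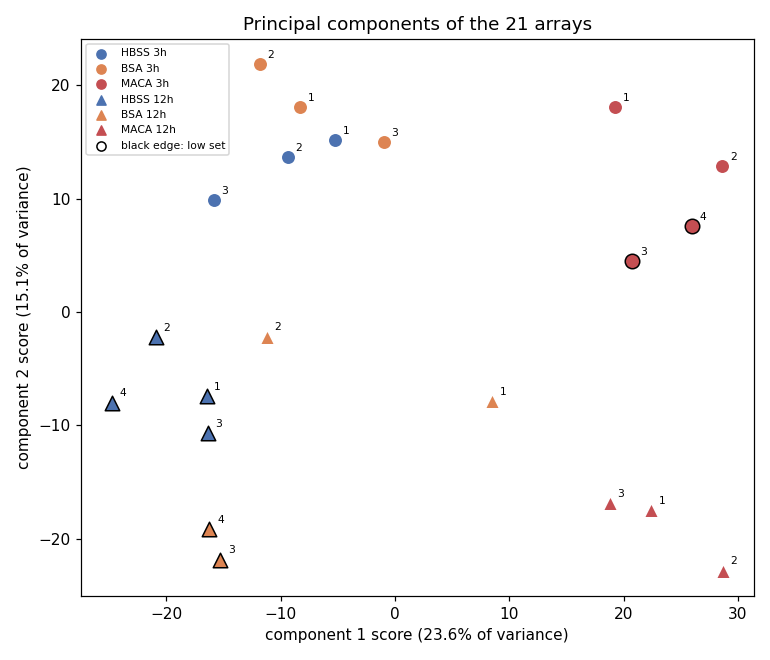
Scores of the 21 arrays on the first (23.6% of variance, x axis) and second (15.1%, y axis) principal components of log2 values, with colours for the 6 groups, circles for 3 h, triangles for 12 h and black edges for the 8 arrays of the low technical set. MACA arrays lie at 18.8 or more on the x axis, and BSA 12 h replicate 1 lies at 8.47.

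At 3 h, chemokine and cytokine transcripts stood far higher in MACA than in vehicle lungs. Il6, an acute phase cytokine, was at least 13.5-fold higher (adjusted p = 0.000105), with log2 values of 9.58 ± 0.78 (SD, n = 4) against 4.87 ± 0.35 (SD, n = 3). Ccl2, which draws monocytes into tissue, rose (log2 fold 4.30 ± 0.50 (SE), adjusted p = 8.2e-05), as did Cxcl1 (log2 fold 4.05 ± 0.71, adjusted p = 0.00246) and Cxcl2 (log2 fold 4.09 ± 0.75, adjusted p = 0.00312), neutrophil chemoattractants. Cxcl10, an interferon-inducible chemokine for T cells, rose too (log2 fold 4.15 ± 0.42, adjusted p = 2.81e-05). Ccl20, a dendritic cell chemokine, was at least 9.78-fold higher (adjusted p = 0.00462). Higher also were Ccl3 (log2 fold 3.80), a macrophage chemokine, Acod1 (at least 6.12-fold higher), which makes itaconate in activated macrophages, and Adamts4 (at least 9.08-fold higher), a protease. Prss22 (at least 11-fold higher), a serine protease, Sfn (at least 6.56-fold higher), stratifin, and Fosl1 (at least 3.65-fold higher), a Fos family factor, rose. The largest falls were in Cckar (log2 fold -2.50, adjusted p = 0.00312), a cholecystokinin receptor, Krtap5-1 (at least 1.08-fold lower, adjusted p = 0.00778), a keratin-associated protein, Klf15 (log2 fold -1.77, adjusted p = 0.00123), a glucocorticoid-induced transcription factor, Zmynd10 (at least 2.16-fold lower, adjusted p = 0.00445), a cilia assembly factor, Cldn8 (at least 2.1-fold lower, adjusted p = 0.00388), a tight junction claudin, and Atp2b2 (at least 2.44-fold lower, adjusted p = 0.00879), a calcium pump. Of 12393 genes, 1006 passed limma's threshold, 600 higher and 406 lower (128 higher and 12 lower without scaling between arrays), and 225 of the higher and 31 of the lower were at least 2-fold. Leaving out HBSS 3 h replicate 2 ended the call of Sfn (adjusted p = 0.0555), and HBSS 3 h replicate 3 that of Krtap5-1 (0.0521).

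Among the lists, NF-kB feedback genes had the highest share past the threshold. 15 of 16 NF-kB feedback genes rose (15 adjusted over the list alone, camera adjusted p = 3.98e-26). They included Tnfaip3 (log2 fold 2.62), a ubiquitin-editing enzyme that limits the pathway, Bcl3 (log2 fold 2.39), Zc3h12a (log2 fold 2.16) and Nfkb2 (log2 fold 1.94). 7 of 13 CXC chemokines rose (7 adjusted over the list alone, camera adjusted p = 5.74e-09). After those above, Cxcl5 (log2 fold 3.22), made by alveolar epithelium, rose most. 9 of 17 CC chemokines rose (12 adjusted over the list alone, camera adjusted p = 3.71e-09). Ccl7 (at least 6.06-fold higher), a monocyte chemoattractant, was one of these. 10 of 17 proinflammatory cytokines rose (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.73e-09). Il1b (log2 fold 3.26) rose, as did Csf2 (log2 fold 2.66), which sustains alveolar macrophages, and Il1rn (log2 fold 2.77), the receptor antagonist opposing Il1b. 9 of 20 STAT and SOCS feedback genes rose (11 adjusted over the list alone, camera adjusted p = 4.68e-09). The largest changes were in Socs3 (log2 fold 1.69), Pim1 (log2 fold 1.69) and Cish (log2 fold 1.50). 14 of 24 immediate early genes rose and 3 fell (15 higher and 3 lower adjusted over the list alone, camera adjusted p = 3.03e-10). After Fosl1, Egr1 (log2 fold 2.38), Atf3 (log2 fold 2.30) and Junb (log2 fold 2.26) rose most. 11 of 23 interferon-stimulated genes rose (15 adjusted over the list alone, camera adjusted p = 2.68e-12). Examples were Gbp3 (log2 fold 1.40), a guanylate-binding protein, Oasl1 (log2 fold 1.30) and Ifi47 (log2 fold 1.29). 7 of 21 matrix and remodelling genes rose (8 adjusted over the list alone, camera adjusted p = 8.88e-06). Mmp8 (log2 fold 2.06), the neutrophil collagenase, and Mmp9 (log2 fold 1.31) were among them. 7 of 16 oxidative stress and metallothionein genes rose (11 adjusted over the list alone, camera adjusted p = 2.8e-07, 0.0563 with correlation estimated). Mt1 (log2 fold 1.54) binds zinc and copper. 9 of 24 acute phase and antimicrobial genes rose (11 adjusted over the list alone, camera adjusted p = 3.44e-07, 0.104 with correlation estimated). Saa1 (at least 5.64-fold higher), a serum amyloid protein, was one. 8 of 21 pattern recognition receptors rose (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.71e-06, 0.152 with correlation estimated). Trem1 (at least 1.33-fold higher), a myeloid receptor, was one. 4 of 21 coagulation and fibrinolysis genes rose (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00609, 0.152 with correlation estimated). Thbs1 (log2 fold 1.52), thrombospondin, was one. 6 of 15 endothelial adhesion and activation genes rose (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0292, 0.208 with correlation estimated). The selectins Sele (at least 4.12-fold higher) and Selp (log2 fold 2.26) and the leukocyte ligand Vcam1 (log2 fold 1.24) rose. 3 of 28 type 2 and alternative activation genes rose (4 adjusted over the list alone, camera adjusted p = 0.0298, 0.152 with correlation estimated). Ccl22 (log2 fold 1.89), a chemokine for helper T cells, was one. That list had camera adjusted p = 0.0645 with the technical set as a term. Leaving out HBSS 3 h replicate 3 ended the calls of Ccl22 (adjusted p = 0.0637) and type 2 and alternative activation genes (0.0946, in 2 of 21 fits), and HBSS 3 h replicate 2 that of endothelial adhesion and activation genes (0.0727, in 2 of 21 fits).

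Among cell type markers at 3 h, 6 of 17 neutrophil markers rose (8 adjusted over the list alone, camera adjusted p = 2.43e-06). S100a8 (log2 fold 2.28), a calprotectin subunit, and Mmp8 were among them. 5 of 16 dendritic cell markers rose (6 adjusted over the list alone, camera adjusted p = 0.00016). Cd83 (log2 fold 2.83, adjusted p = 3.76e-06) and Irf4 (at least 1.5-fold higher) rose. 1 of 13 B cell and plasma cell markers rose (2 adjusted over the list alone, camera adjusted p = 0.000301, 0.157 with correlation estimated). It was Fcer2a (log2 fold 1.49, adjusted p = 0.00643), the low-affinity IgE receptor. Camera also placed 2 lists upwards that had 0 members past limma's threshold over all genes. One was T cell and NK cell markers (4 higher and 1 lower of 21 at unadjusted p under 0.05, camera adjusted p = 0.00033, 0.269 with correlation estimated), the other erythroid and platelet markers (3 higher of 11 at unadjusted p under 0.05, camera adjusted p = 0.0402, 0.152 with correlation estimated). The other 14 lists did not pass camera. In 6 of them 0 members passed limma's threshold, and at unadjusted p under 0.05 were 6 of 15 glucocorticoid-responsive genes (2 adjusted over the list alone, adjusted p = 0.816), 0 of 10 MHC class II genes (0.295), 2 of 18 eosinophil, basophil and mast cell markers (0.985), 5 of 18 alveolar epithelial markers (0.207), 4 of 21 endothelial cell markers (0.337) and 1 of 8 thymus and lymph node markers (0.57). 3 of 16 circadian clock genes rose and 1 fell (4 higher and 4 lower adjusted over the list alone, adjusted p = 0.421). 1 of 25 cell cycle genes rose (adjusted p = 0.923). 1 of 15 complement genes rose (3 adjusted over the list alone, adjusted p = 0.0875). 3 of 18 prostaglandin and leukotriene genes rose and 1 fell (3 higher and 4 lower adjusted over the list alone, adjusted p = 0.856). 1 of 17 macrophage and monocyte markers rose (1 adjusted over the list alone, adjusted p = 0.244, 0.00772 with the set as a term). 1 of 17 airway epithelial markers rose and 1 fell (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.475). 2 of 21 fibroblast and smooth muscle markers fell (2 adjusted over the list alone, adjusted p = 0.886). 1 of 22 cardiac muscle, skeletal muscle, fat and cartilage markers rose (adjusted p = 0.398). The median or mean and the test differed in sign for 3 lists. They were cell cycle genes (median -0.06, test up), prostaglandin and leukotriene genes (mean 0.02, test down) and eosinophil, basophil and mast cell markers (mean -0.03, test up). Of 19 lists that camera called, 10 kept the call with an estimated correlation. Leaving out HBSS 3 h replicate 3 ended the call of S100a8 (adjusted p = 0.0707), and MACA 3 h replicate 1 that of erythroid and platelet markers (0.152, in 3 of 21 fits).

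The count of 1006 became 532 (378 higher and 154 lower) when these 7 arrays were fitted alone. Leaving out HBSS 3 h replicate 1, 2 or 3 gave 577, 640 or 481, and MACA 3 h replicate 4 gave 519. Within the high technical set (2 MACA against 3 HBSS arrays) 552 genes passed, 374 of them shared with the 1006, and with the set as a term 1123 passed, 711 shared.

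**Figure D2:**
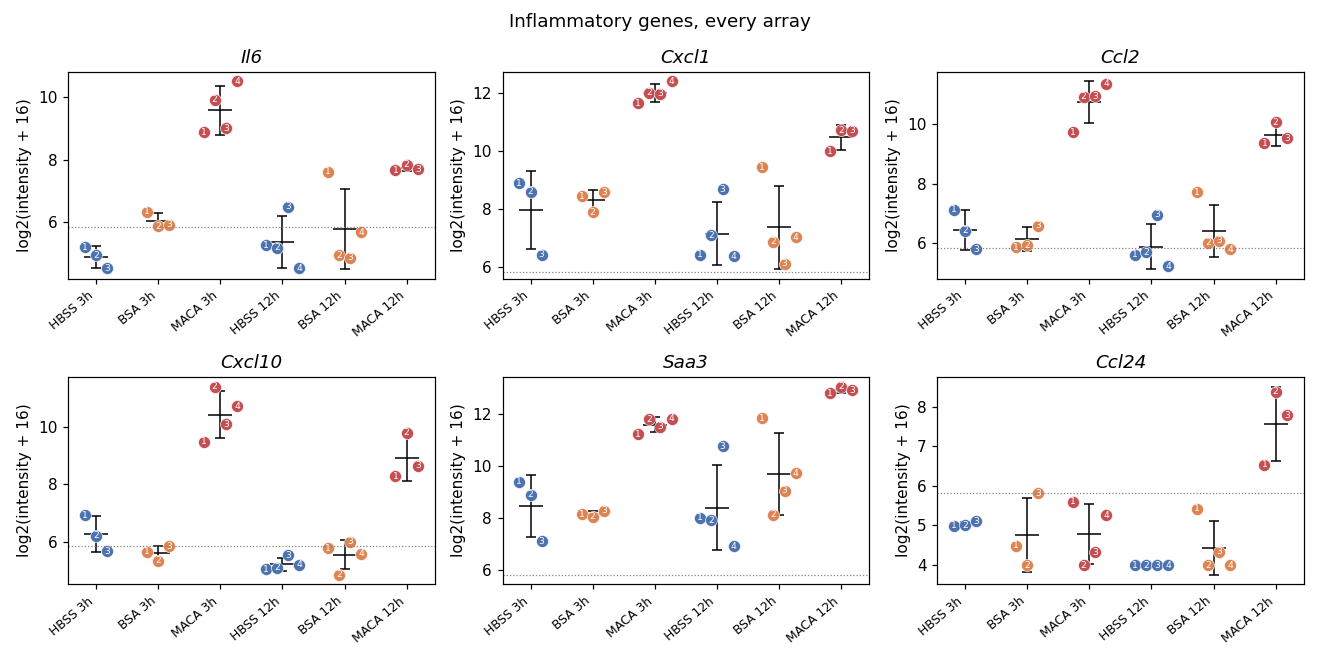
log2(intensity + 16) after quantile normalization (y axis) of 6 inflammatory genes in every array of the 6 groups (x axis), with points for arrays and bars for the group mean ± SD. The mean of Il6 was 9.58 with MACA and 4.87 with HBSS at 3 h, and that of Ccl24 7.56 with MACA and 4.00 with HBSS at 12 h.

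At 12 h, serum amyloid genes and chemokines for monocytes, T cells and eosinophils were among the highest in MACA lungs. Saa1 and Saa3, acute phase apolipoproteins, rose (log2 fold 4.55 ± 0.49 (SE, n = 3 against n = 4), adjusted p = 3.39e-05 and log2 fold 4.51 ± 0.81, adjusted p = 0.00125). Slc26a4, the anion exchanger pendrin (log2 fold 4.27 ± 0.73, adjusted p = 0.000857), and Timp1, an inhibitor of metalloproteinases (log2 fold 3.72 ± 0.49, adjusted p = 0.000146), rose as well. Ccl24, an eotaxin, was at least 3.33-fold higher (adjusted p = 0.000173), with log2 values of 7.56 ± 0.94 (SD, n = 3) against 4.00 ± 0.00 (SD, n = 4). Higher too were Ccl2 (log2 fold 3.79, adjusted p = 0.000141), Cxcl10 (at least 8.39-fold higher, adjusted p = 5.33e-05), Cxcl1 (log2 fold 3.33), Acod1 (at least 7.15-fold higher), Tnfrsf9 (at least 6.29-fold higher), a lymphocyte costimulatory receptor, Gpr84 (at least 4.23-fold higher), a fatty acid receptor, and Tnf (at least 2.7-fold higher). The lowest were Car3 (log2 fold -3.65, adjusted p = 0.00488), a carbonic anhydrase, Gsta2 (log2 fold -3.24, adjusted p = 0.000317), a glutathione transferase, Acaa1b (at least 3.85-fold lower), a peroxisomal thiolase, Bex2 (log2 fold -2.15), Fabp4 (log2 fold -1.95), a fatty acid-binding protein, Sprr2k (at least 1.04-fold lower), Krtap5-1 (at least 1.17-fold lower) and Tcap (log2 fold -1.85), telethonin of the sarcomere. In total 2509 genes passed, 1258 higher and 1251 lower (162 higher and 5413 lower without scaling between arrays), with 257 and 129 at least 2-fold. Leaving out MACA 12 h replicate 2 ended the call of Fabp4 (adjusted p = 0.0977, in 3 of 21 fits). Another probe set, under the noise level, had the opposite sign for Tnfrsf9, Fabp4 and Krtap5-1. The set as a term put adjusted p above 0.05 for Cxcl1 (0.071), Car3 (0.165), Fabp4 (0.557), Sprr2k (0.226) and Krtap5-1 (0.116).

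Nearly the whole interferon list moved at 12 h. 21 of 23 interferon-stimulated genes rose (23 adjusted over the list alone, camera adjusted p = 4.2e-16, 0.0575 with correlation estimated, with the set term 14 higher). The antiviral effectors Ifit1 (log2 fold 1.79), Mx1 (at least 1.96-fold higher) and Oas1a (log2 fold 1.35) were among them. 13 of 20 STAT and SOCS feedback genes rose (16 adjusted over the list alone, camera adjusted p = 1.69e-08, with the set term 9 higher). Socs3 (log2 fold 1.56) and Socs1 (at least 2.02-fold higher) rose. 11 of 16 NF-kB feedback genes rose (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.91e-09, 0.119 with correlation estimated, with the set term 11 higher). Nfkb2 (log2 fold 1.85) and Tnfaip2 (log2 fold 1.59) rose. 13 of 17 CC chemokines rose (13 adjusted over the list alone, camera adjusted p = 1.69e-08, 0.076 with correlation estimated, with the set term 9 higher). Ccl7 (log2 fold 3.14) was one. 7 of 13 CXC chemokines rose (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 4e-05, 0.0739 with correlation estimated, with the set term 5 higher). Cxcl9 (at least 2.52-fold higher), an interferon-gamma target, was one. 12 of 24 acute phase and antimicrobial genes rose (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.18e-07, 0.121 with correlation estimated, with the set term 10 higher). Saa2 (at least 4.16-fold higher) and Steap4 (log2 fold 2.05) rose. 11 of 21 pattern recognition receptors rose (11 adjusted over the list alone, camera adjusted p = 1.32e-07, 0.122 with correlation estimated, with the set term 8 higher). The scavenger receptors Marco (at least 2.33-fold higher) and Msr1 (log2 fold 2.22) rose. 9 of 17 proinflammatory cytokines rose (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 9.02e-05, 0.119 with correlation estimated, with the set term 6 higher). Il1rn (log2 fold 3.01) and Il6 (log2 fold 2.38) rose. 12 of 28 type 2 and alternative activation genes rose (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.9e-05, with the set term 12 higher). Beside Ccl24 these held Arg1 (at least 2.88-fold higher, adjusted p = 0.000415), the arginase of alternatively activated macrophages, Ccl22 (log2 fold 2.78) and Ccl17 (log2 fold 2.31). Clca1, a goblet cell product, did not pass (at least 3.32-fold higher, adjusted p = 0.0528). 8 of 21 matrix and remodelling genes rose and 1 fell (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00479, 0.131 with correlation estimated, with the set term 4 higher, adjusted p = 0.174). Tnc (log2 fold 1.76), tenascin, and Mmp12 (log2 fold 1.73), the macrophage elastase, rose. 4 of 15 complement genes rose and 1 fell (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0102, 0.292 with correlation estimated, with the set term 4 higher). Cfb (log2 fold 2.89) and C3ar1 (log2 fold 1.29) rose. 7 of 25 cell cycle genes rose (7 adjusted over the list alone, camera adjusted p = 0.0319, 0.576 with correlation estimated, with the set term 5 higher). The helicase subunits Mcm5 (log2 fold 1.29) and Mcm6 (log2 fold 1.07) rose. 3 of 10 MHC class II genes rose (5 adjusted over the list alone, camera adjusted p = 0.00453, 0.256 with correlation estimated, with the set term 6 higher). They were H2-DMa (log2 fold 0.79), Ciita (log2 fold 0.50) and Cd74 (log2 fold 0.29), the latter pair with log2 folds of -0.12 and -0.30 without scaling between arrays. Leaving out MACA 12 h replicate 3 ended the call of Ciita (adjusted p = 0.0522), and MACA 12 h replicate 2 that of cell cycle genes (0.201, in 4 of 21 fits). Adjusted p exceeded 0.05 with the set term for Il6 (0.0931) and Mmp12 (0.0572).

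Cell type markers shifted both ways at 12 h. 6 of 16 dendritic cell markers rose (7 adjusted over the list alone, camera adjusted p = 0.0031, 0.121 with correlation estimated, with the set term 6 higher and 1 lower). Batf3 (log2 fold 1.24) and Itgax (log2 fold 1.06) rose. 6 of 13 B cell and plasma cell markers rose (6 adjusted over the list alone, camera adjusted p = 0.00379, 0.286 with correlation estimated, with the set term 6 higher). Fcer2a (log2 fold 2.30) was one. 6 of 17 neutrophil markers rose (7 adjusted over the list alone, camera adjusted p = 0.00453, 0.215 with correlation estimated, with the set term 0 past limma's threshold and 3 at unadjusted p under 0.05). Il1r2 (at least 3.05-fold higher), a decoy receptor, and Lcn2 (log2 fold 1.94) rose. 5 of 17 macrophage and monocyte markers rose and 1 fell (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0319, 0.383 with correlation estimated, with the set term 2 higher and 2 lower, adjusted p = 0.928). Ccr2 (log2 fold 1.32) and Cd68 (log2 fold 1.16) rose and Fabp4 fell. 3 of 21 T cell and NK cell markers rose and 1 fell (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0149, 0.448 with correlation estimated, with the set term 0 past limma's threshold and 2 at unadjusted p under 0.05, adjusted p = 0.387). Ccl5 (log2 fold 1.16) rose and Zap70 (log2 fold -1.43) fell. 7 of 21 fibroblast and smooth muscle markers fell (7 adjusted over the list alone, camera adjusted p = 0.00547, 0.299 with correlation estimated, with the set term 1 higher and 5 lower). The matrix proteins Npnt (log2 fold -1.10) and Lum (log2 fold -1.15) fell. 6 of 22 cardiac muscle, skeletal muscle, fat and cartilage markers fell (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00187, 0.279 with correlation estimated, with the set term 0 past limma's threshold and 5 at unadjusted p under 0.05). Myh6 (log2 fold -1.27) and Myl7 (log2 fold -0.98), the atrial myosin heavy and light chains, were among them. Myh6 lay at 9.48 to 10.04 in MACA 12 h arrays and 10.65 to 11.58 in HBSS 12 h arrays. Leaving out MACA 12 h replicate 2 ended the calls of Ccl5 (adjusted p = 0.0777, in 2 of 21 fits), Zap70 (0.0686) and Myl7 (0.102, in 2 of 21 fits), MACA 12 h replicate 1 those of macrophage and monocyte markers (0.0815, in 2 of 21 fits) and T cell and NK cell markers (0.163, in 2 of 21 fits), and HBSS 12 h replicate 4 that of fibroblast and smooth muscle markers (0.0604). Another probe set had a log2 fold of the opposite sign for Zap70 (0.45). Adjusted p exceeded 0.05 with the set term for Il1r2 (0.06), Lcn2 (0.0734), Ccr2 (0.227), Cd68 (0.196), Ccl5 (0.21), Zap70 (0.276), Myh6 (0.0968) and Myl7 (0.376).

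The other 13 lists did not pass camera at 12 h (adjusted p from 0.0614 to 0.969). 5 of 16 oxidative stress and metallothionein genes rose and 2 fell (5 higher and 4 lower adjusted over the list alone, adjusted p = 0.735). 5 of 24 immediate early genes rose and 3 fell (8 higher and 5 lower adjusted over the list alone, adjusted p = 0.334). 2 of 15 glucocorticoid-responsive genes rose and 6 fell (3 higher and 7 lower adjusted over the list alone, adjusted p = 0.334). 1 of 16 circadian clock genes rose and 4 fell (2 higher and 5 lower adjusted over the list alone, adjusted p = 0.0614). 7 of 21 coagulation and fibrinolysis genes rose and 2 fell (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.0928). 4 of 15 endothelial adhesion and activation genes rose and 2 fell (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.142). 4 of 18 prostaglandin and leukotriene genes rose and 3 fell (4 higher and 3 lower adjusted over the list alone, adjusted p = 0.735). 3 of 18 alveolar epithelial markers rose and 2 fell (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.656). With the set as a term the circadian (adjusted p = 0.0161) and glucocorticoid-responsive lists (0.0193) passed, and over camera's settings their adjusted p ranged from 0.0161 to 0.35 and from 0.0134 to 0.734, while fry, which tests against no change, gave 0.00858 and 0.297. In single genes, Nqo1 (log2 fold -1.58), a quinone reductase, fell while Mt2 (log2 fold 1.96) rose, and Rnase2a (at least 1.61-fold higher), an eosinophil ribonuclease, rose. Tsc22d3 (log2 fold -1.38) and Ednrb (log2 fold -1.32) fell. The medians of oxidative stress and metallothionein genes (-0.10), prostaglandin and leukotriene genes and thymus and lymph node markers (both -0.01) were opposite to their upward tests. The set as a term put adjusted p above 0.05 for Mt2 (0.14). Of 20 lists that camera called, STAT and SOCS feedback genes and type 2 and alternative activation genes kept the call with an estimated correlation.

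Every MACA 12 h array belonged to the high technical set and every HBSS 12 h array to the low set, so no within-set value exists and the set term rests on the groups that hold both. With that term 2008 genes passed, 1125 of them among the 2509 with the same direction, and 99.6% of the 2509 kept their sign. Without MACA 12 h replicate 2 the count of 2509 was 1366.

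**Figure D3:**
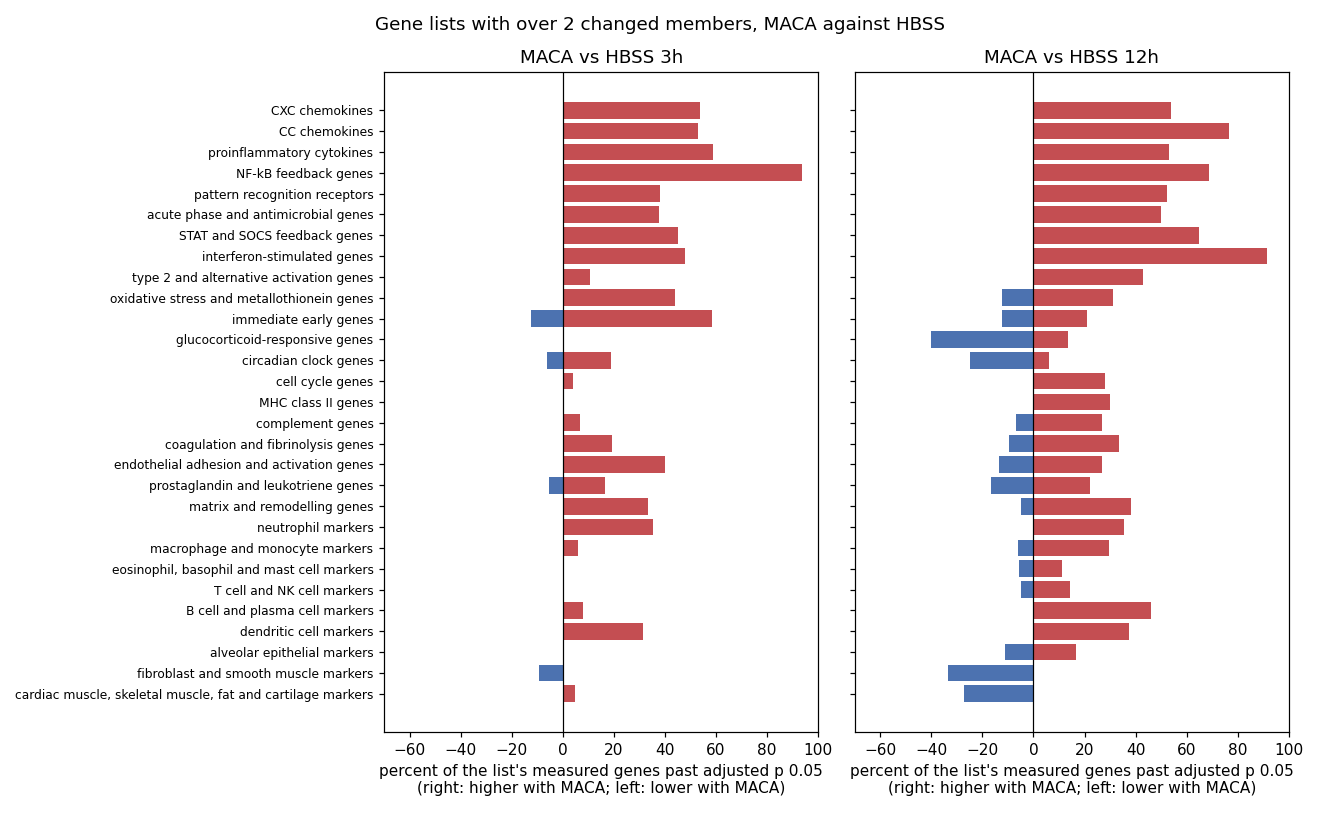
Percent of each list's measured genes past adjusted p 0.05 for MACA against HBSS at 3 h and 12 h (x axis, higher to the right, lower to the left), for lists with over 2 such genes (y axis). At 3 h 15 of 16 NF-kB feedback genes were higher, and at 12 h 21 of 23 interferon-stimulated genes.

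Across times, 295 genes were higher with MACA than HBSS at both 3 h and 12 h (60.9 for independent lists), 121 were lower at both (41 for independent lists) and 18 changed in opposite directions. The response itself differed between times for 484 genes, 256 with a higher fold at 12 h and 228 with a lower one (282 higher and 159 lower with median centring, 22 higher and 2446 lower without scaling). The difference of log2 folds was highest for Ccl24 (difference 3.80, adjusted p = 0.00973), Pigr (difference 2.96, adjusted p = 0.0191), an IgA receptor, Cckar (difference 2.69, adjusted p = 0.0286), Rnase2a (difference 2.56, adjusted p = 0.009) and Tlx2 (difference 2.51, adjusted p = 0.0358). It was lowest for Prss22 (difference -5.70, adjusted p = 0.012), Ccl20 (difference -4.62, adjusted p = 0.0494), Cldn4 (difference -4.44, adjusted p = 0.0168), Fosl1 (difference -4.41, adjusted p = 0.0149) and Gsta2 (difference -4.38, adjusted p = 0.00598). In HBSS 12 h, replicates 1 and 2 lay above 3 and 4 for these 5 (Ccl20 at 7.97 and 8.01 against 5.28 and 6.49), which enlarges the differences, and the first 4 were high with BSA at 3 h too, as given below. These are fitted differences, and where a group lay under the noise level, as Ccl24 did in HBSS lungs, they are no bound. 4 of 24 immediate early genes had a lower fold at 12 h (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 3.48e-06, 0.344 with correlation estimated), and 2 of 16 NF-kB feedback genes did so (8 adjusted over the list alone, camera adjusted p = 3.48e-06, 0.443 with correlation estimated), while 3 of 28 type 2 and alternative activation genes had a higher fold at 12 h (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.026, 0.443 with correlation estimated). The set term left 236 genes, 66 shared in direction. Leaving out 1 array gave 161 (without MACA 12 h replicate 2), 201 (without HBSS 3 h replicate 3), 227 (without HBSS 3 h replicate 1), 261 (without HBSS 12 h replicate 2) and 272 (without MACA 3 h replicate 4). Leaving out MACA 12 h replicate 2 ended the call of Pigr (adjusted p = 0.0544, in 2 of 21 fits), HBSS 3 h replicate 3 those of Cckar (0.071, in 8 of 21 fits), Tlx2 (0.0871, in 12 of 21 fits) and Ccl20 (0.116, in 16 of 21 fits), and HBSS 3 h replicate 2 that of type 2 and alternative activation genes (0.0739, in 2 of 21 fits). The set as a term put adjusted p above 0.05 for Ccl24 (0.0752), Pigr (0.0743), Cckar (0.0672), Rnase2a (0.0691) and Tlx2 (0.629).

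Set against BSA, a foreign protein at the same dose, MACA gave higher chemokine and cytokine transcripts at 3 h, with Ccl20 an exception given below. Cxcl10 was at least 23.9-fold higher (adjusted p = 7.29e-06), and Ccl2 (log2 fold 4.63 ± 0.50 (SE, n = 4 against n = 3), adjusted p = 5.39e-05), Il1b, a pyrogenic cytokine (log2 fold 3.60 ± 0.60, adjusted p = 0.00237), and Il6 (log2 fold 3.55 ± 0.57, adjusted p = 0.00206) were higher. Rgs16 was at least 3.74-fold higher (adjusted p = 0.00017), and so were Cxcl1 (log2 fold 3.72), Cxcl2 (log2 fold 3.96), Ccl3 (at least 10.3-fold higher), Acod1 (at least 6.12-fold higher), Slc26a4 (log2 fold 3.80) and Ccl7 (at least 6.06-fold higher). The lowest included Exosc8 (log2 fold -1.60, adjusted p = 0.00109), an RNA exosome subunit, Rpl27a (log2 fold -1.50, adjusted p = 0.000993), a ribosomal protein, Map3k12 (log2 fold -1.42, adjusted p = 0.00715) and Cep68 (log2 fold -1.11, adjusted p = 0.0144). 16 of 23 interferon-stimulated genes were higher (20 adjusted over the list alone, camera adjusted p = 1.21e-19), 14 of 16 NF-kB feedback genes were higher (15 adjusted over the list alone, camera adjusted p = 2.68e-21) and 9 of 17 proinflammatory cytokines were higher (10 adjusted over the list alone, camera adjusted p = 1.45e-09). Fosl1 (log2 fold -0.17, adjusted p = 0.928), Prss22 (log2 fold 0.03, adjusted p = 1) and Cldn4 (log2 fold 0.31, adjusted p = 0.846), chosen after their values were seen, did not pass. Leaving out BSA 3 h replicate 2 ended the calls of Ccl3 (adjusted p = 0.0521), Slc26a4 (0.0526) and Cep68 (0.0667, in 3 of 21 fits). Another probe set had a log2 fold of the opposite sign for Cep68 (0.18), as had one under the noise level for Rpl27a.

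In all 738 genes differed between MACA and BSA at 3 h, 434 higher and 304 lower (386 higher and 429 lower with median centring, 41 higher and 3 lower without scaling), and 9 of 18 lists called by camera kept the call with an estimated correlation. With HBSS in place of BSA 288 of them were also higher and 113 also lower. Independent lists would share 21 and 9.96. Simulated unchanged groups sharing the MACA arrays gave 0 higher in both with limma, which their construction fixes. The covariance of the folds was 0.107, against 0.0185 in the simulation, and their correlation 0.732, against 0.429. With different MACA arrays in either comparison, 57 to 123 genes were higher in both (2.23 to 6.56 for independent lists) with a covariance of 0.0887 to 0.0943. Within the high set (2 MACA against 3 BSA arrays) 152 passed, 117 shared, and with the set as a term 567, 408 shared. The 7 arrays alone gave 132 (113 higher and 19 lower). Without BSA 3 h replicate 1 or 2 the count was 273 or 218. Without MACA 3 h replicate 2, 3 or 4 it was 473, 459 or 323.

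At 12 h, MACA exceeded BSA in serum amyloid and chemokine genes: Saa1 (log2 fold 4.24 ± 0.49 (SE, n = 3 against n = 4), adjusted p = 0.000182), Ccl2 (log2 fold 3.26 ± 0.50, adjusted p = 0.00118) and Cxcl10 (log2 fold 3.35 ± 0.42, adjusted p = 0.000429). Gpr84 was at least 4.23-fold higher (adjusted p = 7.62e-05), Ccl24 was at least 3.33-fold higher (adjusted p = 0.00124) and Cxcl9 at least 2.52-fold higher (adjusted p = 0.000613), and so were Tnf (at least 2.7-fold higher), Cxcl1 (log2 fold 3.11) and Slc26a4 (log2 fold 3.02). Lower were Car3 (log2 fold -3.88, adjusted p = 0.00738), Gsta2 (log2 fold -2.38, adjusted p = 0.00608), Acaa1b (at least 3.47-fold lower), Bex2 (log2 fold -1.92), Tcap (log2 fold -2.00) and Scara5 (log2 fold -1.86), a ferritin receptor. Tnfrsf9 and Acod1 passed too (log2 means 8.48 against 5.14 and 8.67 against 5.08), with BSA means under the noise level. 13 of 23 interferon-stimulated genes were higher (18 adjusted over the list alone, camera adjusted p = 1.88e-15), 10 of 17 CC chemokines were higher (12 adjusted over the list alone, camera adjusted p = 3.71e-10) and 8 of 28 type 2 and alternative activation genes were higher (11 adjusted over the list alone, camera adjusted p = 3.33e-05). 7 of 22 cardiac muscle, skeletal muscle, fat and cartilage markers were lower (10 adjusted over the list alone, camera adjusted p = 7.38e-05, 0.192 with correlation estimated), and 6 of 21 fibroblast and smooth muscle markers were lower (8 adjusted over the list alone, camera adjusted p = 0.00285, 0.312 with correlation estimated). BSA 12 h replicate 1 held high inflammatory values next to the other 3 arrays of its group, in log2 values chosen after they were seen: Cxcl1 9.44 against 6.11 to 7.01, Saa3 11.82 against 8.12 to 9.71, and Acod1 8.16 against 4.00 to 4.18. Leaving out MACA 12 h replicate 2 ended the calls of Cxcl1 (adjusted p = 0.0601) and Slc26a4 (0.0704). Another probe set, under the noise level, had the opposite sign for Tnfrsf9 and Scara5.

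The count at 12 h was 1196, 504 higher and 692 lower (30 higher and 66 lower without scaling), and 4 of 16 lists called by camera kept the call with an estimated correlation. Against HBSS 436 of the higher and 509 of the lower genes passed too (51.2 and 69.9 for independent lists, 0 higher by construction in simulated unchanged groups with limma, covariance 0.142 against 0.0244, correlation 0.837 against 0.57). With 3 MACA arrays no split kept enough on each side, so part of the excess can come from the shared arrays. On these 7 arrays alone limma called 0 genes, with 2439 at unadjusted p under 0.05. Within the high set (3 MACA against 2 BSA arrays) 429 passed, 276 shared, with the set as a term 760, 645 shared. The count was 398 without MACA 12 h replicate 2 and 797 or 698 without BSA 12 h replicate 3 or 4.

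The pooled fit called few genes between BSA and vehicle at 3 h, and the 6 arrays fitted alone called more, as given below. The pooled fit takes 1 spread for each gene from all 6 groups. That spread holds the differences between 12 h control arrays, which were wide for Fosl1, Prss22 and Cldn4. Gjb2, a gap junction connexin, rose (log2 fold 1.76 ± 0.20 (SE, n = 3 against n = 3), adjusted p = 0.000727), as did Chac1, which degrades glutathione (log2 fold 1.84 ± 0.30, adjusted p = 0.0144), and Krt15, a keratin of basal cells, was at least 1.01-fold higher (adjusted p = 0.0209). Fosl1 was at least 4.12-fold higher (adjusted p = 0.0209), and Artn, a neurotrophic ligand, at least 2.24-fold higher (adjusted p = 0.0131). In all 22 genes passed, 20 higher and 2 lower, and the lower pair, Cer1 and Havcr1, lay under the noise level in both groups. Without scaling limma called 0, with 409 at unadjusted p under 0.05. Chosen after their values were seen, 6 genes that did not pass had these log2 means ± SD: Prss22 (9.26 ± 0.36 against 5.32 ± 0.39, adjusted p = 0.0608), Ccl20 (8.86 ± 0.49 against 4.57 ± 0.51, adjusted p = 0.08), Sfn (8.49 ± 0.28 against 5.02 ± 0.66, adjusted p = 0.116), Cldn4 (8.40 ± 0.56 against 5.90 ± 0.17, adjusted p = 0.171), Ccl2 (6.12 ± 0.40 against 6.44 ± 0.67, adjusted p = 0.894) and Il6 (6.03 ± 0.26 against 4.87 ± 0.35, adjusted p = 0.534). All 20 higher and 2 lower genes also passed for MACA against HBSS in the same direction (0.968 and 0.0655 for independent lists, 0 higher in simulated unchanged groups with limma, covariance 0.0523 against 0.0246, correlation 0.466 against 0.536). The correlation of the folds lay below that of the simulation. The 3 shared HBSS arrays were too few to split, so part of the overlap can come from them. Leaving out BSA 3 h replicate 2 ended the calls of Chac1 (adjusted p = 0.0752, in 5 of 21 fits), Krt15 (0.149, in 5 of 21 fits) and Fosl1 (0.124, in 5 of 21 fits), and HBSS 3 h replicate 2 that of Artn (0.0769, in 4 of 21 fits).

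Camera called 5 lists here, and 0 kept the call with an estimated correlation. Among them 1 of 24 immediate early genes rose (2 adjusted over the list alone, camera adjusted p = 0.0344, 0.997 with correlation estimated), namely Fosl1. In the other 4 lists 0 members passed limma's threshold over all genes: oxidative stress and metallothionein genes (8 higher of 16 at unadjusted p under 0.05, 4 adjusted over the list alone, camera adjusted p = 9.34e-05, 0.615 with correlation estimated) and NF-kB feedback genes (4 higher of 16 at unadjusted p under 0.05, 4 adjusted over the list alone, camera adjusted p = 0.00109, 0.997 with correlation estimated) upwards, interferon-stimulated genes (1 lower of 23 at unadjusted p under 0.05, camera adjusted p = 0.0287, 0.997 with correlation estimated) and endothelial cell markers (4 lower of 21 at unadjusted p under 0.05, camera adjusted p = 0.0122, 0.615 with correlation estimated) downwards. All 6 arrays lay in the high set, which fitted alone gave 189 genes, 20 shared. The 6 arrays alone gave 78, the set as a term 54, 22 shared. The count was 7 or 9 without HBSS 3 h replicate 1 or 2. It was 8 or 9 without BSA 3 h replicate 2 or 3, and 37 or 48 without BSA 12 h replicate 1 or 3. Leaving out HBSS 3 h replicate 3 ended the calls of immediate early genes (adjusted p = 0.219, in 3 of 21 fits) and NF-kB feedback genes (0.08), BSA 3 h replicate 3 that of interferon-stimulated genes (0.451, in 3 of 21 fits), and BSA 3 h replicate 1 that of endothelial cell markers (0.052). The set as a term put adjusted p above 0.05 for immediate early genes (0.0549).

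At 12 h, lymphocyte genes were among those higher with BSA than with vehicle: Ltb, lymphotoxin beta (log2 fold 1.02 ± 0.18 (SE, n = 4 against n = 4), adjusted p = 0.0173), Blk, a B cell kinase (log2 fold 0.92 ± 0.21, adjusted p = 0.047), and Itgb7, a lymphocyte integrin (log2 fold 0.86 ± 0.17, adjusted p = 0.0288). Snrnp40, a splicing factor (log2 fold -1.10 ± 0.24, adjusted p = 0.0382), Fli1, a transcription factor (log2 fold -1.02 ± 0.23, adjusted p = 0.0418), and Ap2a1, a clathrin adaptor (log2 fold -1.02 ± 0.23, adjusted p = 0.0416), fell. The changes were small: of 167 genes, 69 were higher and 98 lower (14 higher and 41 lower with the mean of probe sets, 6 higher and 2051 lower without scaling), and 1 and 5 reached 2-fold. The replicate block in these 8 arrays ended all 6 calls (adjusted p = 0.166 to 0.235) and left all 7 list calls below. 1 of 13 B cell and plasma cell markers rose (9 adjusted over the list alone, camera adjusted p = 3.83e-06, 0.674 with correlation estimated). Camera also called T cell and NK cell markers (7 higher of 21 at unadjusted p under 0.05, 4 adjusted over the list alone, camera adjusted p = 0.00171, 0.691 with correlation estimated), interferon-stimulated genes (8 higher of 23 at unadjusted p under 0.05, 4 adjusted over the list alone, camera adjusted p = 0.00463, 0.691 with correlation estimated), MHC class II genes (5 higher of 10 at unadjusted p under 0.05, 4 adjusted over the list alone, camera adjusted p = 0.00828, 0.691 with correlation estimated), neutrophil markers (3 higher of 17 at unadjusted p under 0.05, camera adjusted p = 0.0225, 0.691 with correlation estimated) and STAT and SOCS feedback genes (4 higher of 20 at unadjusted p under 0.05, 2 adjusted over the list alone, camera adjusted p = 0.0362, 0.691 with correlation estimated) upwards and glucocorticoid-responsive genes (3 lower of 15 at unadjusted p under 0.05, camera adjusted p = 0.0131, 0.691 with correlation estimated) downwards, each with 0 members past limma's threshold over all genes. Of the BSA genes, 45 were also higher and 75 also lower with MACA (7 and 9.89 for independent lists, 0 higher in simulated unchanged groups with limma, covariance 0.0587 against 0.0187, correlation 0.534 against 0.469). The 4 HBSS arrays were shared, so part of this can come from them. Leaving out HBSS 12 h replicate 2 ended the calls of Ltb (adjusted p = 0.0676), Blk (0.168, in 14 of 21 fits), Itgb7 (0.0937, in 5 of 21 fits), Snrnp40 (0.128, in 8 of 21 fits), Fli1 (0.151, in 14 of 21 fits) and Ap2a1 (0.11, in 12 of 21 fits), HBSS 12 h replicate 4 those of T cell and NK cell markers (0.0509), interferon-stimulated genes (0.0509) and MHC class II genes (0.0509), BSA 12 h replicate 1 those of neutrophil markers (0.333, in 2 of 21 fits) and STAT and SOCS feedback genes (0.338, in 4 of 21 fits), and HBSS 12 h replicate 1 that of glucocorticoid-responsive genes (0.153, in 3 of 21 fits). Another probe set had a log2 fold of the opposite sign for Snrnp40 (0.12) and Fli1 (0.17). Adjusted p exceeded 0.05 with the set term for T cell and NK cell markers (0.19), interferon-stimulated genes (0.19), neutrophil markers (0.222) and STAT and SOCS feedback genes (0.379).

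Fosl1, Prss22 and Cldn4 varied between replicates of the 12 h control groups, in log2 values chosen after they were seen. In HBSS 12 h, Fosl1 lay at 6.32 and 6.34 in replicates 1 and 2 and 4.00 and 4.38 in replicates 3 and 4, and in BSA 12 h at 6.77, 6.83, 4.00 and 4.95 in the same order. Prss22 lay at 8.04, 7.64, 5.08 and 5.39 in HBSS 12 h and 8.21, 8.31, 5.59 and 5.20 in BSA 12 h, and Cldn4 at 8.27, 8.04, 6.02 and 6.07 and 8.52, 8.44, 6.50 and 5.76. Prss22 lay at 4.66 to 5.02 in MACA 12 h arrays, and at 3 h at 8.88 to 9.58 with MACA, 8.89 to 9.59 with BSA and 4.91 to 5.68 with HBSS. Replicates 1 and 2 of both groups deviated together, as did 3 and 4: with the replicate block in these 8 arrays limma called 0 genes (2154 at unadjusted p under 0.05), without it 3, and with the block in all 21 arrays 213. Within the low set (2 BSA against 4 HBSS arrays) 283 passed, 52 shared, with the set as a term 1493, 167 shared. Without HBSS 12 h replicate 2, 3 or 4 the count was 4, 28 or 73. Without BSA 12 h replicate 1, 2, 3 or 4 it was 75, 338, 55 or 36.

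**Figure D4:**
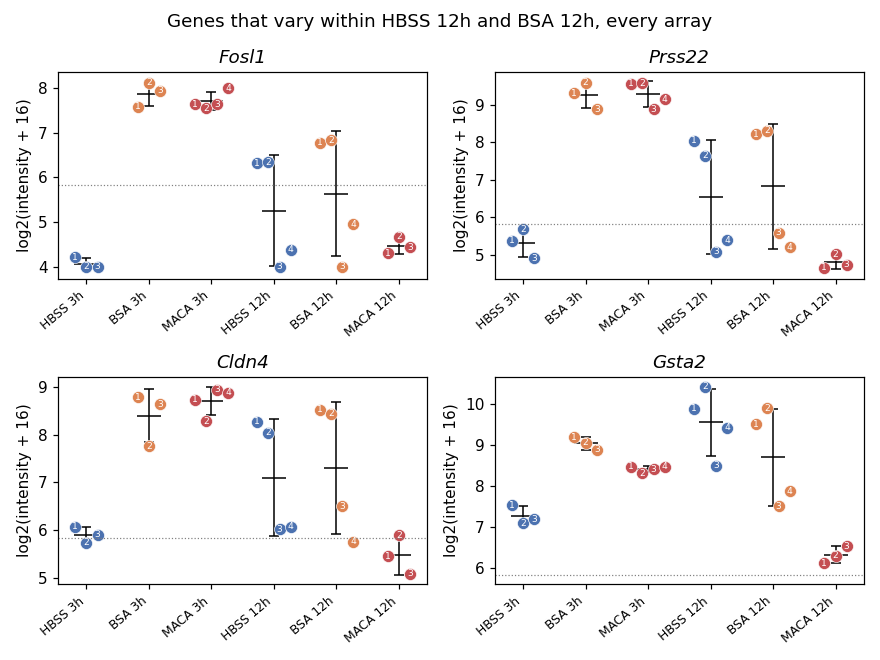
log2(intensity + 16) after quantile normalization (y axis) of Fosl1, Prss22, Cldn4 and Gsta2 in every array of the 6 groups (x axis), with points for arrays and bars for the group mean ± SD. In HBSS 12 h, Prss22 lies at 8.04 and 7.64 in replicates 1 and 2 and at 5.08 and 5.39 in replicates 3 and 4.

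Between 3 h and 12 h, clock genes changed in every treatment. In vehicle lungs Dbp, a clock output transcription factor, fell (log2 fold -5.22 ± 0.29 (SE, n = 4 against n = 3), adjusted p = 3.35e-08), as did Nr1d1, a nuclear receptor that represses Arntl (log2 fold -4.02 ± 0.56, adjusted p = 0.000773), Per2 (log2 fold -2.77 ± 0.40, adjusted p = 0.000972) and Hlf (log2 fold -2.50 ± 0.34, adjusted p = 0.000693), while Arntl was at least 7.4-fold higher (adjusted p = 7.52e-06) and Npas2 at least 4.96-fold higher (adjusted p = 9.57e-07). Dbp was at least 28.4-fold lower (adjusted p = 4.43e-08) at 12 h than at 3 h with MACA, and fell with BSA (log2 fold -5.12 ± 0.29, adjusted p = 4.47e-08). With HBSS 4 of 16 circadian clock genes rose and 10 fell (4 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.000171, 0.0553 with correlation estimated), with MACA 3 of 16 rose and 10 fell (4 higher and 10 lower adjusted over the list alone, camera adjusted p = 2.34e-05) and with BSA 3 of 16 rose and 10 fell (4 higher and 10 lower adjusted over the list alone, camera adjusted p = 1.83e-07). Spon2, the matrix protein mindin, rose with HBSS (log2 fold 3.17 ± 0.29), MACA (log2 fold 2.83 ± 0.29) and BSA (log2 fold 2.93 ± 0.29). Zbtb16, a glucocorticoid-induced zinc finger protein, fell with HBSS (log2 fold -2.72 ± 0.45) and BSA (log2 fold -3.30 ± 0.45). With MACA, Arg1 (at least 2.88-fold higher), Ccl24 (at least 3.33-fold higher), Clca1 (at least 3.32-fold higher) and Cckar (log2 fold 2.74) rose, and Prss22 (at least 11-fold lower), Cldn4 (log2 fold -3.24) and Car3 (log2 fold -3.75) fell. Also with MACA, 11 of 16 NF-kB feedback genes fell (13 adjusted over the list alone, camera adjusted p = 1.2e-10, 0.153 with correlation estimated) and 7 of 24 immediate early genes fell (8 adjusted over the list alone, camera adjusted p = 4.34e-06, 0.153 with correlation estimated). Leaving out MACA 12 h replicate 2 ended the call of Clca1 (adjusted p = 0.194, in 16 of 21 fits).

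With time 1331 genes changed with MACA (693 higher, 638 lower), 977 with HBSS (504 higher, 473 lower) and 657 with BSA (418 higher, 239 lower). Median centring gave 334 higher and 534 lower with HBSS and 308 higher and 275 lower with BSA, and no scaling 7624 higher and 44 lower with HBSS and 11 higher and 12 lower with BSA. Within the high set MACA gave 849 (628 shared) and BSA 180 (118 shared). HBSS has no within-set value, with 3 h arrays high and 12 h low. The set as a term gave 1282 genes with MACA, 1222 with HBSS and 313 with BSA, of which 950, 399 and 252 were shared, and on the groups compared alone 698 passed with MACA and 25 with BSA. With MACA the count was 666 or 878 without MACA 12 h replicate 2 or 3. With HBSS it was 327, 608 or 540 without HBSS 3 h replicate 1, 2 or 3, and 438 without HBSS 12 h replicate 2. With BSA it was 318 or 156 without BSA 3 h replicate 1 or 2. Without BSA 12 h replicate 2, 3 or 4 it was 1008, 298 or 329.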

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

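The tests of the 3 patterns were chosen, with their bounds, after the results were seen, and the splits of the arrays were set before. In groups of 4 arrays, 136 sets of values of named genes were tested for an array far from the others, and 7 stood out where chance gives about 1 in 20 (6.8). In log2 values the 7 were Saa1 at 7.50 (others 4.73 to 5.13), Acod1 at 8.16 (others 4.00 to 4.18) and Ccl2 at 7.72 (others 5.79 to 6.08) in BSA 12 h replicate 1, Bex2 at 8.51 (others 9.10 to 9.22) in BSA 12 h replicate 4, Acod1 at 5.12 (others 4.00 to 4.08) and Tnfrsf9 at 5.62 (others 4.00) in HBSS 12 h replicate 3, and Crocc at 4.47 (others 4.00) in MACA 3 h replicate 2, the last 3 under the noise level with the others at or near the floor, which fixes the measure. The MACA to HBSS difference changed between 3 h and 12 h, by the interaction test, by 3.80 for Ccl24, 2.96 for Pigr, 2.69 for Cckar, 2.56 for Rnase2a, 2.51 for Tlx2, -5.70 for Prss22, -4.62 for Ccl20, -4.44 for Cldn4, -4.41 for Fosl1 and -4.38 for Gsta2 (log2), the last 5 enlarged by HBSS 12 h replicates 1 and 2.

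The first pattern was that 20 genes, among them Fosl1, Gjb2, Chac1 and Krt15, were higher with BSA than with HBSS at 3 h. The division into technical sets is argued against as the cause, since 0 of the 6 arrays lie in the low set, but within the high set the control ratio did not overlap (1.63 to 1.74 with BSA, 1.81 to 1.91 with HBSS, as in 10% of splits by chance), so a graded technical difference stays open. A condition that varies between lungs whatever was instilled stays open: 19 of the 20 (48.9% of all genes) were higher on average in HBSS 12 h replicates 1 and 2 than in replicates 3 and 4, a division noticed in these genes, and 13 of them (18.1% of all genes) in both replicates, with a median difference of 0.22 against a median log2 fold of 1.10 with BSA. Another hour of harvest also stays open, since 7 of 14 clock genes lay nearer to their 3 h level in replicates 1 and 2 of HBSS 12 h and 8 in those of BSA 12 h, and its bound was moved to under 50% after the value was seen. The BSA given may equally be the source, and with 3 arrays in each group these cannot be told apart.

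The second pattern was the 386 genes at least 2-fold and 2123 genes less than 2-fold different between MACA and HBSS at 12 h, where the technical set coincides with the groups. A first test, on the sign for MACA against BSA in the high set, used the MACA arrays that chose the genes and was replaced: genes called without 1 MACA array had the same sign in that array against the 2 BSA 12 h arrays of the high set for 86.4% to 94.9% of the larger and 80% to 94.4% of the smaller changes, and single 3 h BSA and HBSS arrays against their groups agreed or disagreed in sign for at most 73.3% and 73.6%. These values argue against the division into sets as the whole cause of either part. A graded technical effect stays open: control ratios were 1.13 to 1.22 (HBSS), 1.62 and 1.66 (these BSA arrays) and 1.74 to 1.90 (MACA). With the set as a term 261 of the larger and 864 of the smaller changes were called in the same direction, the median log2 fold falling from 1.28 (median SE 0.26) to 1.20 (0.327) and from 0.505 (0.124) to 0.441 (0.157), so calls ended with smaller folds and wider errors. The set term may not hold for the HBSS 12 h arrays, as given above. An added part from the set stays open, and an effect of MACA remains a candidate explanation.

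The third pattern was that BSA 12 h replicate 1 lay towards the MACA arrays, at a median position of 0.575 over the genes at least 2-fold higher with MACA, where 0 is the HBSS 12 h mean and 1 the MACA 12 h mean. An array that belongs to MACA 12 h is argued against, since over the genes at least 2-fold lower the position was 0.363 and the MACA arrays lay at 0.884 to 1.16. The bound for this test (0.61, the lowest MACA array less the range of the 3) was set after the value was seen, and the bound first tried (0.3) left it open. The technical set is argued against by BSA 12 h replicate 2, of the same set, at 0.135. A mixture with a MACA 12 h lung stays open: its share, in linear intensities, was 0.313, 0.28 and 0.375 over the CXC chemokines, NF-kB feedback genes and cytokines that rose, 0.074 over type 2, -0.002 over interferon-stimulated genes and 0.685 over neutrophil markers, which goes against a single share, as does its range over the lists, 2.655 times that of the widest other BSA 12 h array with the MACA mean as that lung and 5.19 and 4.129 times with replicates 2 and 3, but with replicate 1 it was 1.636 times, under a bound of 2 set, like the test, after comparisons of 2 lists gave either answer, and a stronger response of 1 animal may equally be the source and was not tested.

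Other splits of the same arrays into groups of the same sizes were counted. Only the real split, 1 of 35, gave as many genes for MACA against HBSS at 3 h (1006, highest other 612). The same held at 12 h (2509, highest other 384) and for MACA against BSA at 3 h (738, highest other 523). It held over time for MACA (1331, highest other 298), HBSS (977, highest other 6) and BSA (657, highest other 578). This lowest possible share, unadjusted over comparisons, argues against chance without excluding it. The splits for MACA against HBSS at 12 h and HBSS over time also parted the technical sets. For the change between times few drawn splits, 2 of 100, gave as many (484, highest other 519), but chance is not excluded. For BSA against HBSS at 12 h 2 of 35 splits did (167, highest other 326), so chance cannot be excluded. The highest other split set replicates 1 and 2 of both groups against 3 and 4 (blocked values above). Of the 8 splits that part all 4 numbered pairs only the real one gave as many, but 8 are too few for a share under 0.05, and the highest other split parts 0 pairs. For MACA against BSA at 12 h 2 of 35 splits gave as many (1196, highest other 1401), so chance cannot be excluded by this count. That other split placed BSA 12 h replicate 1 with the MACA arrays. For BSA against HBSS at 3 h the 10 splits are too few for a share under 0.05 (1 gave as many, 22, highest other 2).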

How the results depend on the processing

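The alternatives with no scaling, the technical set and a block within the 12 h control arrays were chosen after seeing the data. Quantile normalization of log2 values, both other log offsets, the variance trend and the filter on the dimmest 30% of genes left each count within 1.5 times, and median centring moved 1 count (63 for BSA against HBSS at 12 h). The mean of probe sets gave 55 for BSA against HBSS at 12 h, and all probe sets singly, where more features were tested, gave 3857 for MACA against HBSS at 12 h, 34 for BSA against HBSS at 3 h, 267 for BSA against HBSS at 12 h, 2063 for MACA over time and 1569 for HBSS over time. With only the groups compared, which leaves fewer arrays to estimate the spread, the counts were 532 for MACA against HBSS at 3 h, 78 for BSA against HBSS at 3 h, 3 for BSA against HBSS at 12 h, 132 for MACA against BSA at 3 h, 0 (limma, 2439 at unadjusted p under 0.05) for MACA against BSA at 12 h, 698 for MACA over time and 25 for BSA over time. Array weights gave 107 for BSA against HBSS at 3 h, 83 for BSA against HBSS at 12 h, 1810 for HBSS over time and 362 for BSA over time. With no scaling the counts were 140 for MACA against HBSS at 3 h, 5575 for MACA against HBSS at 12 h, 0 (limma, 409 at unadjusted p under 0.05) for BSA against HBSS at 3 h, 2057 for BSA against HBSS at 12 h, 44 for MACA against BSA at 3 h, 96 for MACA against BSA at 12 h, 93 for MACA over time, 7668 for HBSS over time, 23 for BSA over time and 2468 for the change between times, and the median log2 fold of all genes moved by -0.57 for MACA against HBSS at 12 h, 0.13 for BSA against HBSS at 3 h, -0.48 for BSA against HBSS at 12 h, 0.72 for HBSS over time and -0.66 for the change between times. Without scaling 6 log2 folds of MACA against HBSS at 12 h turned negative: Ciita -0.12, Cd74 -0.30, Cd247 -0.013, Aqp5 -0.074, Sftpd -0.18 and Robo4 -0.21, on the side to which that median moved. With that set as a term the counts were 54 for BSA against HBSS at 3 h, 1493 for BSA against HBSS at 12 h, 760 for MACA against BSA at 12 h, 313 for BSA over time and 236 for the change between times. Within the high set they were 552 for MACA against HBSS at 3 h, 189 for BSA against HBSS at 3 h, 152 for MACA against BSA at 3 h, 429 for MACA against BSA at 12 h, 849 for MACA over time and 180 for BSA over time, and within the low set 283 for BSA against HBSS at 12 h. The cause was not tested except where the construction is given. The replicate block gave 305 for the change between times, and changed no other count by over 1.5 times, with 213 for BSA against HBSS at 12 h. Outside that comparison the numbers pair no arrays, with same-numbered pairs correlating at -0.13 to 0.16. All 3 same-numbered pairs correlated best with their own number for MACA against HBSS at 3 h and HBSS over time. The block fitted within the 12 h control arrays gave 0 (limma, 2154 at unadjusted p under 0.05) for BSA against HBSS at 12 h. Fits without 1 array, named in parentheses, gave 481 (HBSS 3 h replicate 3) to 1180 for MACA against HBSS at 3 h, 1366 (MACA 12 h replicate 2) to 2670 for MACA against HBSS at 12 h, 7 (HBSS 3 h replicate 1) to 48 (BSA 12 h replicate 3) for BSA against HBSS at 3 h, 4 (HBSS 12 h replicate 2) to 338 (BSA 12 h replicate 2) for BSA against HBSS at 12 h, 218 (BSA 3 h replicate 2) to 922 for MACA against BSA at 3 h, 398 (MACA 12 h replicate 2) to 1670 for MACA against BSA at 12 h, 666 (MACA 12 h replicate 2) to 1455 for MACA over time, 327 (HBSS 3 h replicate 1) to 1124 for HBSS over time, 156 (BSA 3 h replicate 2) to 1008 (BSA 12 h replicate 2) for BSA over time and 161 (MACA 12 h replicate 2) to 570 for the change between times. Of 427 results of named genes, 17 calls ended and 2 arose with median centring, 23 calls ended and 3 arose with log2(value + 1), 23 calls ended and 8 arose with the mean of probe sets, 8 calls ended and 23 arose with array weights, 67 calls ended and 18 arose with the set as a term, 89 calls ended and 14 arose with only the groups compared and 103 calls ended and 19 arose with no scaling, and 0 reversed outside the latter. Within the high set 60 calls ended and 2 arose and within the low set 5 ended, and all 10 of BSA against HBSS at 12 h ended with the block within the 12 h control arrays. Lists were also tested, some settings added after seeing the data, in all but the variance trend and the fits within 1 set, and 1 called list reversed: macrophage and monocyte markers for MACA against HBSS at 12 h with the set as a term (adjusted p = 0.928, median log2 fold -0.074). fry kept 18 of 19 and 18 of 20 lists for MACA against HBSS, and 0 of 5 and 1 of 7 for BSA against HBSS. Signal over background limits genes under the noise level to bounds.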

Other observations

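The lists were fixed beforehand, and those described here were chosen after their values were seen. Camera called glucocorticoid-responsive genes downwards from 3 h to 12 h in each treatment, but not with an estimated correlation. With HBSS 5 of 15 fell (8 adjusted over the list alone, camera adjusted p = 2.65e-05, 0.866 with correlation estimated), with MACA 9 of 15 fell (11 adjusted over the list alone, camera adjusted p = 1.13e-06, 0.349 with correlation estimated) and with BSA 8 of 15 fell (11 adjusted over the list alone, camera adjusted p = 1.91e-10, 0.208 with correlation estimated). Zbtb16, a zinc finger protein, was among them with HBSS (log2 fold -2.72 ± 0.45, adjusted p = 0.0026) and with BSA (log2 fold -3.30 ± 0.45, adjusted p = 0.000662). With the technical set as a term the list's adjusted p with HBSS was 0.249.

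With BSA camera called these lists upwards at 12 h against 3 h, but not with an estimated correlation. 7 of 13 B cell and plasma cell markers rose (11 adjusted over the list alone, camera adjusted p = 8.54e-07, 0.209 with correlation estimated), and 4 of 21 T cell and NK cell markers rose (7 adjusted over the list alone, camera adjusted p = 1.06e-05, 0.494 with correlation estimated). 5 of 23 interferon-stimulated genes rose (7 adjusted over the list alone, camera adjusted p = 0.00329, 0.767 with correlation estimated), and 1 of 10 MHC class II genes rose (7 adjusted over the list alone, camera adjusted p = 0.000804, 0.437 with correlation estimated). For MACA against HBSS the difference of the changes with time had camera adjusted p = 0.507 for glucocorticoid-responsive genes (0.0192 with the set as a term, 0.0192 to 0.931 over camera's settings). For BSA it was not tested.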
